A study of Mus musculus with 4 samples.

How the data were processed

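Single-cell RNA sequencing of mouse fetal cells labelled as lung was read from 1 deposited count matrix of 31053 genes and 43351 cells, with 1 library in each of 4 groups. The groups were the 2 embryonic ages with a Cyp27a1+/- or a Cyp27a1-/- mother, and all fetuses were labelled Cyp27a1-/-. The library name of the E18.5 fetuses of the heterozygous mother carries a wild-type tag that its genotype label does not, and the genotype label was used. The values are UMI counts per gene and cell as deposited by the authors: whole numbers, with an integer field in the file header and cell sums equal to the deposited totals per cell. Per the submitters' processing notes the reads were processed with Cell Ranger 3.0.0 against mm10 and with Seurat 4.3.0, with no order or settings given. No cell had under 500 UMIs, so a filter came before deposit. The deposited gene and cell files carry each other's names, which was settled from their contents. No cell types of the authors were in the files.

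Cells of each age were clustered apart from the other age, both libraries together, with scanpy 1.11.5 under Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0). Counts were scaled and logged, 2000 variable genes and 30 principal components were kept, and a graph of 20 neighbours was cut with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 1, seed 1. A cluster took the name of a marker list when at least 3 of its genes were found in at least 10% of cells and at 4 times the 25th percentile of clusters. Clusters of over 50% called doublets or a mitochondrial median over 20%, and clusters of low UMI count with no marker among the top 10 genes, stayed unnamed. So did clusters with genes of another tissue, or with more markers of another class, among the top 10 genes. This naming rule was revised after the clusters had been seen. Scrublet, run through scanpy, called 0.0605% and 0.186% of cells doublets at E14.5, too few to be of use, and 4.26% and 6.65% at E18.5. Cells with Y-linked UMIs and no Xist UMI were taken as male, and the reverse as female: 819 and 726 male with 1507 and 2052 female cells at E14.5, and 5395 and 3875 male with 22 and 4411 female cells at E18.5.

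Counts were summed over the cells of a class in each library and divided by the class total. Ratios are null mother over heterozygous mother on CPM. Log2 ratios used a pseudocount of 10 CPM; ratios given as folds used none, and a floor of 3 counts stood in for 0. A gene was measured with at least 50 UMIs in the library with the higher CPM, and a class needed 50 cells in both libraries. A gene with 50 UMIs has an interval of 37.1 to 65.9 UMIs, which is the precision at the minimum. Class totals ran from 1208801 UMIs in E14.5 erythroid cells to 53408377 UMIs in E18.5 immune cells. Each gene interval is exact for its Poisson counts, and intervals of list medians come from 200 Poisson draws.

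The 4 planned classes were epithelium, mesenchyme, endothelium and immune cells. Hepatocyte-like and erythroid classes and 3 blood cell types were added after the cells had been seen. Of the gene lists, 44 were written before the data were opened, 13 after, and 2 for tests of explanations. A list median needed at least 3 measured members, and was set against 10000 random lists. These were drawn for each member from about 100 genes on each side of it in mean expression. A median was called outside when its percentile was under 2.5 or over 97.5. Named genes, fixed beforehand, are the 3 with the largest and 3 with the smallest log2 ratio per class, 5 each over all non-erythroid cells, and the 4 farthest members of called lists, with haemoglobin, Xist, Y-linked, mitochondrial, predicted and Rik genes left out of the ranking. The genes that show the tissue of the libraries (Nkx2-1, Sftpc, Tcf21, Alb, Afp, S100a8 and Vpreb1), the embryonic globins, and Igfbp1, Lpin1 and Angptl4 in the closing section were chosen after values were seen. The lists that hold Cyp7a1, Cyp3a11, G6pc and Pck1 were among those written after the data were opened.

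Of 323 values of a list in a class, 89 are reported. They are called lists that apply to all cells or to the class at hand, the cholesterol list in each class, and 19 chosen after main values were seen. That rule looks at the main value and the kind of list only, but it was set after the alternatives had been computed. It replaced a first selection picked by hand with knowledge of which results changed sign, which was dropped for that reason. The closing section also gives counts over the full set. Single-gene values of 1 gene were left out of the text and a figure on request, and it stays in the list medians. The alternatives were 9 planned for the class ratios (2 other scalings, a pseudocount of 1 CPM, minimums of 10 and 200 UMIs, means over cells, no cells above the 95th percentile of UMIs, only cells with at least 1000 genes and under 10% mitochondrial UMIs, and clusters at equal weights), shares without erythroid cells, and 4 added later: male cells, female cells at E14.5, no called doublets at E18.5, and clusters at a resolution of 0.6. Equal weights means that a cluster had the same weight in both libraries, the mean of its UMI shares in them. Clusters did not all weigh the same, and those with few cells in either library were left out.

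The calculation was tested on simulated data made from E14.5 mesenchyme with 11686 measured genes. The intervals held the true ratio for 95.3% of unchanged genes and 92.0% to 94.0% of genes changed by 2 or 4 times. Of 200 lists of unchanged genes 4.50% lay outside, and of 20 lists of doubled genes 100% lay above. The simulated genes were independent, with list members picked at random and no variation beyond counting. These values therefore do not give the rate of false calls for the reported lists. Gene positions are from the mm10 annotation of GENCODE release M21. Figures were drawn with matplotlib 3.10.9.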

Results

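Single-cell transcriptomes were available from 4 libraries of mouse fetal cells, 1 library per group, and each library was labelled as lung. All fetuses were labelled Cyp27a1-/-. CYP27A1 makes 27-hydroxycholesterol and takes part in bile acid synthesis, so such fetuses have no enzyme of their own, and their mothers were labelled either Cyp27a1+/- or Cyp27a1-/-. The design asks how the mother's genotype relates to the cells of a fetus that lacks the enzyme, at the embryonic days labelled E14.5 and E18.5. There were no replicates, so no test between groups was possible. Intervals of genes and shares are exact 95% Poisson or Clopper-Pearson intervals, and those of list medians come from Poisson draws. All cover counting error only, not differences between litters, fetuses or preparations. Values are named by the mother: the heterozygous mother is Cyp27a1+/- and the null mother is Cyp27a1-/-.

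At E14.5 the library of the heterozygous mother held 4957 cells and 47005276 UMIs, and that of the null mother 4843 cells and 53293964 UMIs. The libraries labelled E18.5 held 17034 cells and 97894048 UMIs for the heterozygous mother, and 16517 cells and 118054232 UMIs for the null mother. Cells of the null mother's library were deeper at both ages. The median cell had 3697 UMIs and 1511 genes against 6387 UMIs and 2008 genes at E14.5, and 3782.5 UMIs and 970 genes against 4848 UMIs and 1452 genes at E18.5. Median mitochondrial shares were 2.64% and 2.72% at E14.5, and 2.13% and 2.41% at E18.5. Haemoglobin took 2.44% and 3.82% of UMIs at E14.5, and 14.2% and 5.92% at E18.5. The E18.5 library of the heterozygous mother held almost no female cells, with Xist, which is transcribed in female cells, at 0.347 CPM (UMIs per 1e6 UMIs of the library or class) against 261 CPM in that of the null mother; the E14.5 libraries had 561 and 611 CPM.

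Cyp27a1 (ENSMUSG00000026170, mm10 chromosome 1, 74713574 to 74737892) was detected in every library. Over all cells it had 878 UMIs (18.7 CPM) with the heterozygous mother and 1049 UMIs (19.7 CPM) with the null mother at E14.5. In the libraries labelled E18.5 it had 3766 UMIs (38.5 CPM, interval 37.3 to 39.7) and 4402 UMIs (37.3 CPM, 36.2 to 38.4). The ratio of null over heterozygous was 1.05 (0.962 to 1.15) at E14.5 and 0.969 (0.928 to 1.01) at E18.5. The tags come from the 3' end and may lie outside the deleted part, and no wild-type library stood beside them, so these values do not check the genotype labels.

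The tissue of the libraries labelled E18.5 went against their label. Lung genes were nearly missing and liver genes were abundant. Nkx2-1, the transcription factor of lung epithelium, had 1935 and 2804 UMIs at E14.5 but 4 and 1 UMIs at E18.5. Sftpc, which encodes surfactant protein C, was at 280 and 1444 CPM at E14.5 and at 1.53 and 0.669 CPM at E18.5. Tcf21, a gene of lung fibroblasts, was at 55.5 and 46.4 CPM against 0.337 and 0.313 CPM. Albumin (Alb) was at 0.574 and 0.469 CPM at E14.5 and at 2905 and 8344 CPM at E18.5, and Afp had 48 and 32 UMIs at E14.5 and 139673 and 556924 UMIs at E18.5. S100a8 of neutrophils was at 17740 and 17598 CPM, and the B cell precursor gene Vpreb1 at 168 and 158 CPM. In what follows, the libraries labelled E18.5 are described by these contents, and the values from them do not describe lung.

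**Figure D1:**
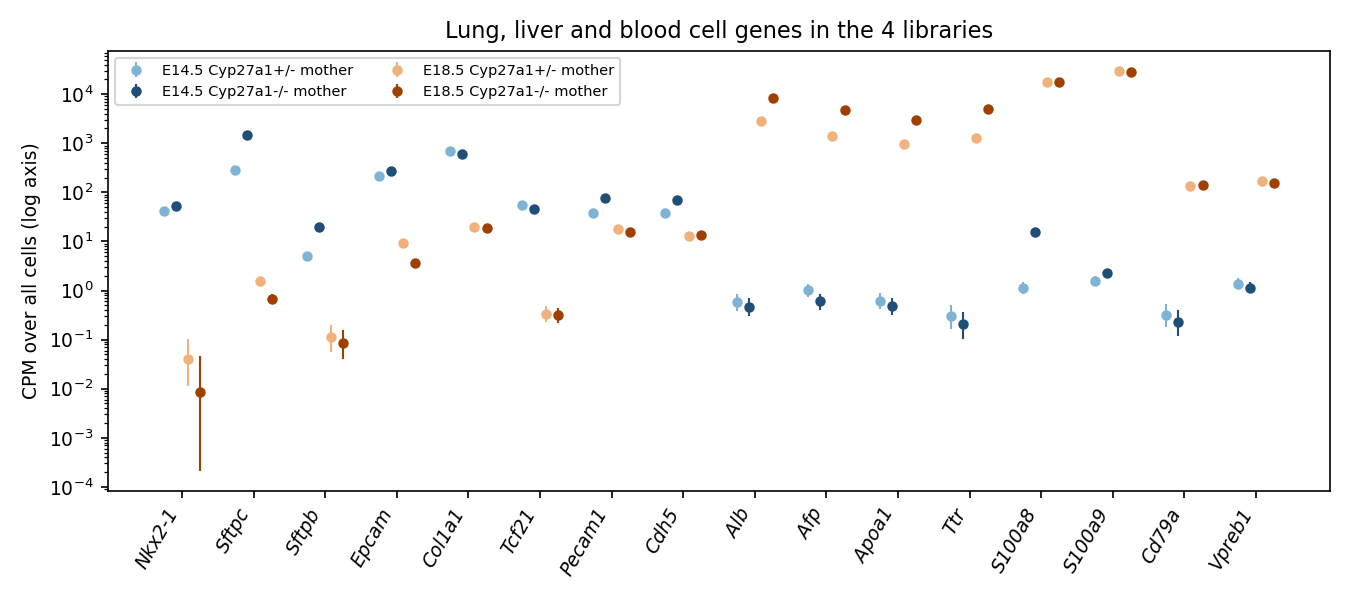
Points show CPM over all cells of a library on a log axis, for lung, liver and blood cell genes; colours mark the 4 groups and bars the exact 95% Poisson intervals. Nkx2-1 had 1935 and 2804 UMIs at E14.5 and 4 and 1 UMIs at E18.5, where Alb reached 2905 and 8344 CPM.

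The first comparison was of the kinds of cells. At E14.5 the library of the null mother had more epithelium, endothelium and immune cells per cell sampled, and about as much named mesenchyme. Epithelium made up 5.45% (4.83 to 6.12) of cells with the heterozygous mother and 9.79% (8.96 to 10.7) with the null mother. Endothelium made up 11.7% (10.8 to 12.6) and 15.4% (14.4 to 16.5), and mesenchyme 39.7% (38.4 to 41.1) and 39.3% (37.9 to 40.7). Immune cells were 124 and 211, a share 1.74 times as large with the null mother. Cells with mesothelium genes were at 2.18% and 0.619%, and heart muscle cells at 1.78% and 0.888%. Unnamed cells, mostly of low depth, made up 35.6% and 24.4%. The largest unnamed cluster had 7 of 9 mesenchyme markers and held 1076 and 461 cells, so the near equal shares of mesenchyme rest on the rule by which clusters were named. Unnamed clusters 8 and 16 each had 7 of 7 epithelium markers. Cluster 8, with thymic genes among its leading genes, held 194 and 206 cells, and cluster 16 held 87 and 122 cells. The size of the difference in epithelium therefore depends on that rule too. In the libraries labelled E18.5, hepatocyte-like cells made up 5.14% (4.81 to 5.48) and 15.6% (15.1 to 16.2), erythroid cells 35.4% (34.7 to 36.1) and 20.1% (19.4 to 20.7), and endothelium-like cells 3.35% (3.09 to 3.63) and 3.05% (2.79 to 3.32). Immune cells made up 46.3% (45.5 to 47.0) and 48.0% (47.2 to 48.7), a ratio of 1.04 that was 0.838 without erythroid cells in the denominator and 0.973 among cells with at least 1000 genes. Unnamed cells made up 9.67% and 13.2%. The largest unnamed cluster was deep, with a median of 16546 UMIs, and held 564 and 820 cells. Its leading genes included Cited4 and Col5a1, as did those of a cluster named erythroid. The erythroid shares thus rest on the naming rule as well.

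**Figure D2:**
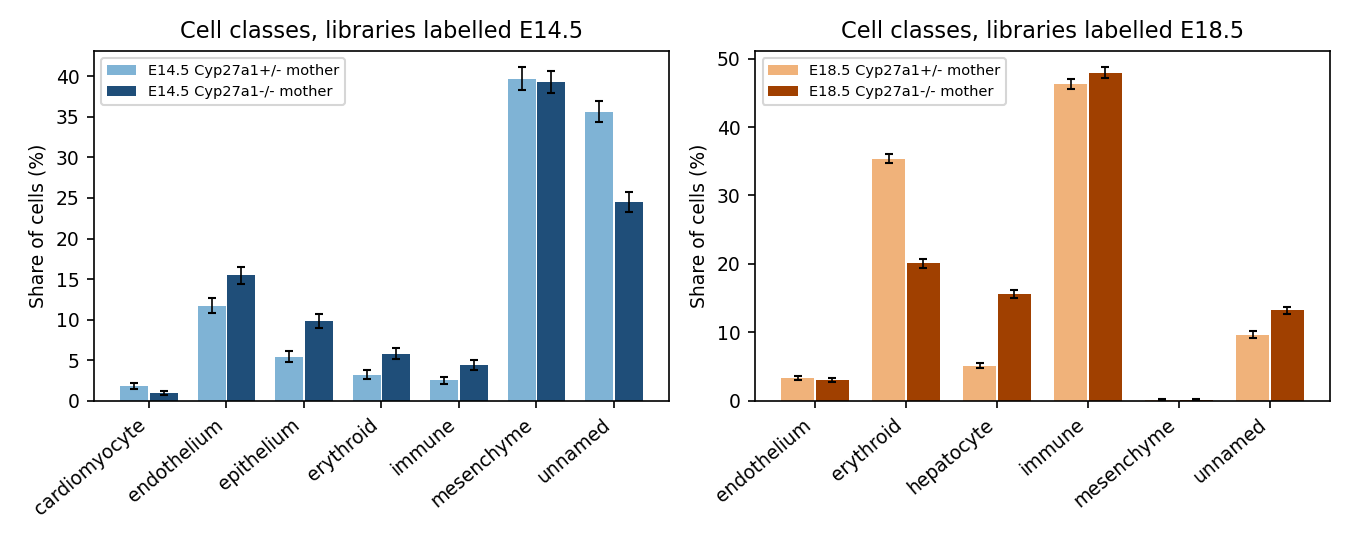
Bars show the share of cells in each class, in percent, with exact binomial 95% intervals, for the libraries labelled E14.5 (left) and E18.5 (right). Epithelium was at 5.45% and 9.79% at E14.5, and hepatocyte-like cells were at 5.14% and 15.6% at E18.5.

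For gene programmes, each list's median log2 ratio of CPM, null over heterozygous mother, was set against 10000 random lists of matched expression. Main list medians given in this report lay outside the central 95% of the random lists unless said otherwise. Where an alternative way of processing put a median inside, its call is said to have ended, with the value there, or the range of values for 4 or more alternatives. An ended call does not by itself mean a smaller value. Over all non-erythroid cells at E14.5, the genes farthest up with the null mother were Sftpc, Scgb3a2, Lyz2, Lgals3 and Clic3, all of epithelium or macrophages, and those farthest down were Myl7, Nppa, Spp1, Myl4 and Myh6, of which 4 belong to heart muscle. In the libraries labelled E18.5, those farthest up were Aqp8, Ttr, Apoa2, Marco and Serpina6, of hepatocytes and liver macrophages, and those farthest down were Ctrb1, Fabp2, Apoa4, Mcpt8 and Prap1, of gut, pancreas and basophils. Such ratios mix shares of cells with levels within cells. The classes are therefore taken one at a time.

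In E14.5 epithelium, genes of differentiated lung cells were higher with the null mother. This held for both kinds of alveolar cell and for ciliated cells. Genes of DNA replication, of Wnt signalling and of the endoplasmic reticulum stress response were lower. The epithelium was 270 cells and 474 cells, with 6898415 and 11378268 UMIs. Of the 8 measured genes of alveolar type 1 (AT1) cells, which form the gas exchange surface, 7 were higher, with a median of 0.58. They included Ager (65.5 to 163 CPM, 2.49-fold, 2.24 to 2.76), Clic5 (2.61 to 15.4 CPM), Hopx (28.7 to 66.9 CPM) and Cldn18 (404 to 667 CPM). Of the 8 measured genes of alveolar type 2 (AT2) cells and surfactant, 6 were higher, with a median of 0.53. Sftpc (mm10 chromosome 14, 70520949 to 70524081) was at 1754 and 6418 CPM, a ratio of 3.66 (3.59 to 3.73), Napsa at 1.16 and 19.2 CPM, Sftpb at 29.9 and 84.8 CPM and Lamp3 at 2.90 and 8.96 CPM. Of 5 genes of ciliated cells 4 were higher, with a median of 0.57, among them Foxj1 (2 and 106 UMIs, 32.1-fold, 8.68 to 269), Dynlrb2 (1 and 92 UMIs, 55.8-fold, 9.76 to 2227) and Rsph1 (8 and 75 UMIs). Tekt1 of the same list (7.39 and 11.2 CPM) went the other way among female cells. The general epithelium genes moved little, with a median of 0.11, and Cldn7 (273 to 335 CPM) was the farthest. Lists of other cells were higher in this class as well, mesenchyme at 0.45 with 5 of 5 and erythroid at 2.61 with 6 of 6, both looked at after values were seen; free RNA and doublets were not set apart. The mesenchyme call ended as a mean over cells (0.18), without cells above the 95th percentile of UMIs (0.13) and among male cells (0.79).

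Among programmes in E14.5 epithelium, the immediate early and heat shock genes had a median of 0.31 with 10 of 12 higher, led by Egr1 (59.9 to 144 CPM) and Junb (32.6 to 80.5 CPM); these genes also respond to handling of tissue. Targets of the sterol receptor LXR had a median of 0.27 with 5 of 6 higher, and glucocorticoid targets 0.11 with 7 of 10 higher, a call that ended under 5 alternatives (-0.01, when clusters had equal weights, to 0.10). The S phase genes had a median of -0.17 with 15 of 16 lower, the Wnt targets -0.24 with 7 of 7 lower, and the unfolded protein response -0.21 with 11 of 13 lower. The S phase call ended without cells above the 95th percentile of UMIs (-0.10), at equal weights (-0.12) and among male cells (-0.12), and the Wnt call without the same top cells (-0.17). That of the unfolded protein response ended among female cells (-0.071), that of LXR targets among male cells (0.27), and that of the epithelium list at equal weights (0.075) and among female cells (0.056). The cholesterol synthesis and uptake genes had a median of -0.08 with 17 of 23 lower, inside the central 95% of random lists. The 3 genes with the largest ratios were Scgb3a2 of airway secretory cells (39.1 to 219 CPM), Clic3 (76 and 999 UMIs) and Sftpc, and those with the smallest were Col2a1 (82.8 to 31.1 CPM), Ly6h (128 to 55.2 CPM) and Ntm (70.3 to 36.7 CPM). The cluster with Scgb3a2 and Sox2 among its leading genes held 21.5% of the epithelium with the heterozygous mother and 30.4% with the null mother.

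In E14.5 mesenchyme, genes of the extracellular matrix were higher with the null mother, and genes of DNA replication and cholesterol synthesis were lower by small amounts. The class was 1969 and 1903 cells. Globin RNA in it differed as well: adult globins were higher with the null mother, such as Hbb-bs (120 to 821 CPM). The embryonic Hbb-y was lower (44.3 to 20.3 CPM), and carry-over of red cell RNA was not tested. The cluster holding the largest part differed: cluster 1, of dividing cells, held 28.4% of the class with the heterozygous mother, and cluster 2, led by Mfap4, held 23.8% with the null mother. Of 10 elastic fibre genes 8 were higher, with a median of 0.34. Elastin (Eln, mm10 chromosome 5, 134702593 to 134747323) was at 205 and 478 CPM, a ratio of 2.33 (2.26 to 2.40), with Mfap4 at 670 and 1301 CPM, Lox at 91.6 and 145 CPM and Fbn1 at 102 and 149 CPM. Of 10 collagen genes 9 were higher, with a median of 0.27, led by Col6a3 (54.4 to 91.3 CPM) and Col6a2 (201 to 316 CPM). The general mesenchyme genes had a median of 0.18 with 8 of 9 higher, the lipofibroblast genes 0.18 with 5 of 7 higher, and the Wnt targets 0.15 with 6 of 9 higher. The Wnt and lipofibroblast calls ended at equal weights of clusters (0.015 and 0.072) and as means over cells (0.10 and 0.14), and the lipofibroblast and mesenchyme calls among male cells (0.093 and 0.10).

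The smooth muscle genes of E14.5 mesenchyme had a median of 0.26 with 6 of 7 higher, led by Aspn (7.86 to 20.6 CPM), but the median was -0.22 when clusters had equal weights and -0.01 as a mean over cells, where the call ended. The mesothelium genes had a median of -0.51 with 6 of 6 lower, led by Upk3b (62.5 to 26.7 CPM), and 0.10 at equal weights; the mesothelium cluster held 5.49% of the class with the heterozygous mother and 1.58% with the null mother. The heart muscle genes, a list chosen for this class after its values were seen, had a median of -0.39 with 4 of 4 lower. Heart muscle cells were in these libraries, and carry-over of their RNA was not tested. The S phase genes had a median of -0.19 with 16 of 16 lower, the unfolded protein response -0.14 with 10 of 13 lower, and the cholesterol synthesis and uptake genes -0.11 (-0.16 to -0.09) with 18 of 23 lower. The 3 genes with the largest ratios were G0s2 (30.8 to 100 CPM), Sftpc (7.96 to 32.9 CPM, a gene of epithelium) and Eln. Those with the smallest were Hmga2, a growth gene of early fetal tissue (62.2 to 16.2 CPM), Myl7 (31.3 to 6.25 CPM) and Igfbp2 (48.4 to 16.6 CPM).

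In E14.5 endothelium, general endothelial and general capillary genes were higher with the null mother, and aerocyte, lymphatic, matrix and cholesterol genes were lower. The class was 580 and 748 cells, and its depth differed: cluster 3, of low depth, held 66.4% of it with the heterozygous mother, and cluster 4, of high depth, held 55.1% with the null mother. Of 9 endothelial genes 9 were higher, with a median of 0.28, led by Pecam1 (316 to 429 CPM). Of 5 general capillary genes 5 were higher, with a median of 0.35, led by Gpihbp1, the capillary anchor of lipoprotein lipase (41.0 to 116 CPM, 2.82-fold, 2.43 to 3.28). The 3 measured arterial genes had a median of 0.41, and 5 interferon genes of 5 were higher, with a median of 0.33. The 4 aerocyte genes had a median of -0.45, led by Fibin (54 and 9 UMIs). Fibin was also among the leading genes of mesenchyme cluster 2, and carry-over of mesenchymal RNA was not tested. Tbx2 of the aerocyte list went the other way among male cells (0.18). The arterial call ended as a mean over cells (0.18), and the arterial and interferon calls without cells above the 95th percentile of UMIs (0.20 and 0.29). The lymphatic genes had a median of -0.41 with 4 of 5 lower, led by Ccl21a (234 to 23.1 CPM) and Prox1 (90 and 14 UMIs).

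The cholesterol synthesis and uptake genes of E14.5 endothelium had a median of -0.17 with 15 of 21 lower, and -0.06 as a mean over cells, which was inside the central 95% of random lists. The unfolded protein response had a median of -0.19 with 12 of 13 lower, and its call ended among male cells (-0.11). Lists of matrix and mesenchyme, looked at in this class after values were seen, were lower: the mesenchyme genes at -0.54 with 5 of 6 lower, the elastic fibre genes at -0.59 with 8 of 8 lower, and the collagens at -0.33 with 5 of 7 lower. Carry-over of mesenchymal RNA was not tested. The mesenchyme median was 0.23 among male cells and -0.055 as a mean over cells, with its call ended in both, the elastic fibre median -0.08 as a mean over cells, where its call ended, and the collagen median was 0.06 at a minimum of 200 UMIs, 0.02 as a mean over cells, with its call ended in both, and 0.67 among male cells. The 3 largest ratios were of Sftpc (12.8 to 81.9 CPM, a gene of epithelium), Gpihbp1 and Scn7a (61.8 to 163 CPM), and the 3 smallest of Ccl21a, Eln (186 to 34.1 CPM) and Fn1 (92.6 to 17.0 CPM).

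**Figure D3:**
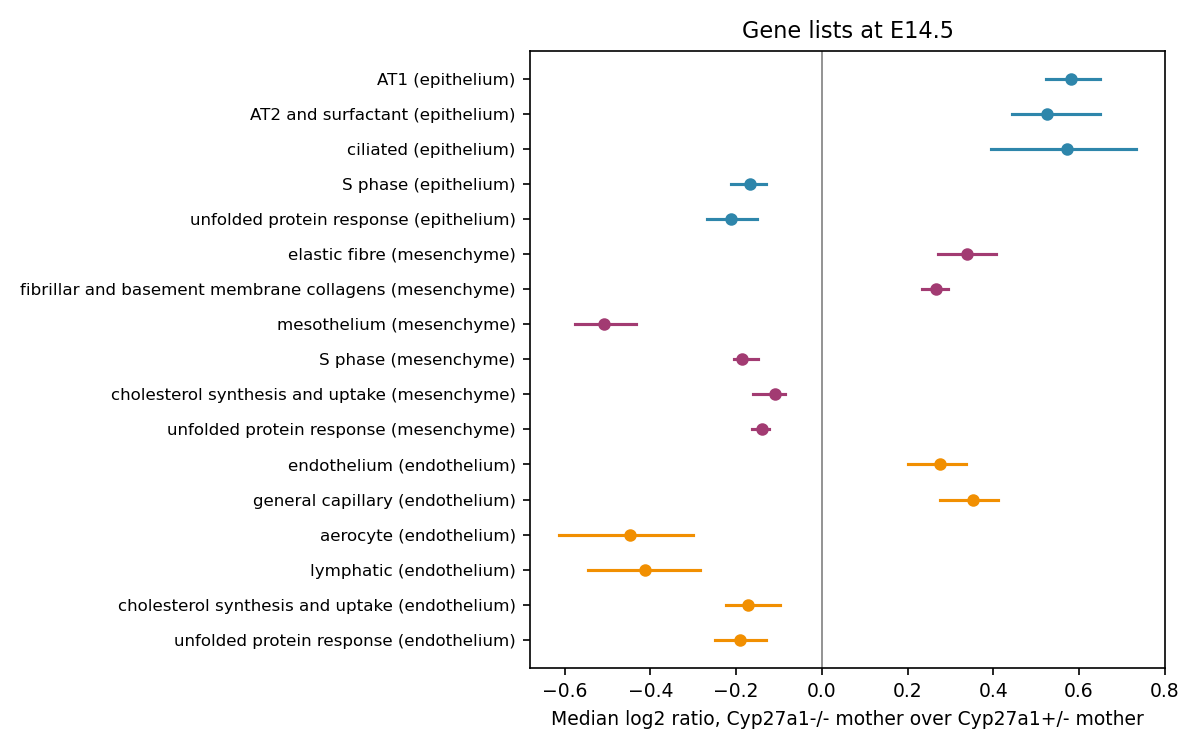
Points show the median log2 CPM ratio of a gene list at E14.5, null over heterozygous mother, with the class in brackets and colour; bars are 95% counting intervals. The AT1, AT2 and ciliated medians of epithelium lie between 0.53 and 0.58, and the cholesterol medians of mesenchyme and endothelium at -0.11 and -0.17.

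E14.5 immune cells were few, 124 and 211, so that a handful of cells set most values. Neutrophil and monocyte genes had a median of 1.42 with 3 of 4 higher, S100a8 at 15.8 and 238 CPM, while Retnlg of the same list had 75 and 0 UMIs, at least 62.7-fold lower. The unfolded protein response had a median of -0.24 with 9 of 11 lower, and the S phase genes -0.17 with 13 of 15 lower. The G2 and M phase genes had a median of 0.23 with 14 of 16 higher, which was -0.31 as a mean over cells. The interferon genes had a median of 0.39 with 5 of 7 higher, which was -0.01 among male cells, where the call ended, the immediate early genes 0.19 with 9 of 13 higher, which was -0.59 among male cells, and the lymphoid genes 0.28 with 4 of 5 higher, which was -0.91 among female cells. The calls of G2 and M phase, immediate early, interferon and lymphoid genes ended without cells above the 95th percentile of UMIs (-0.066, 0.19, 0.29 and 0.31), and that of S phase among female cells (-0.19). The G2 and M phase call also ended at equal weights of clusters (0.077), the immediate early and lymphoid calls at a minimum of 200 UMIs (0.15 and 0.34), and the lymphoid call in cells with at least 1000 genes (0.23). The cholesterol list had a median of 0.24 with 13 of 17 higher, inside the central 95% of random lists. The largest ratios were of S100a8, Ly6d (3.77 to 65.3 CPM) and Mgp (18.1 to 143 CPM, reversed as a mean over cells), and the smallest of Spp1 (913 to 9.62 CPM), H2-Aa (152 to 5.11 CPM) and H2-Ab1 (156 to 6.32 CPM).

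E14.5 erythroid cells, 159 and 280, were not among the classes planned. The median over all genes was 0.20, but -0.31 as a mean over cells and -0.053 without cells above the 95th percentile of UMIs, so ratios there carry a shift whose sign depends on the processing. The 3 largest ratios were of Tmem14c (13 and 258 UMIs), Sftpc (18 and 159 UMIs) and Hist1h2ap (3 and 50 UMIs, 9.42-fold, 3.04 to 47.2), and the 3 smallest of Tmcc2 (107 to 25.7 CPM), Slc2a1 (77 and 31 UMIs) and Pim1 (51.3 to 13.6 CPM). The embryonic globins did not move together. Hbb-y was at 21315 and 3843 CPM and Hba-x at 3670 and 1496 CPM, lower with the null mother, while Hbb-bh1 had 63 and 289 UMIs and was higher (2.59-fold, 1.97 to 3.46). Over whole libraries, embryonic transcripts made up 4.74% (4.69 to 4.79) of beta-globin UMIs with the heterozygous mother and 1.31% (1.29 to 1.33) with the null mother.

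In the libraries labelled E18.5, hepatocyte-like cells showed the clearest programme. Genes of cholesterol and fatty acid synthesis were higher with the null mother. Bile acid synthesis genes were lower by a small amount. G6pc and Pck1, both enzymes of glucose production, were lower by a large one. This class, 875 and 2579 cells, was not planned, since the libraries were labelled lung, and its all-gene median was 0.0957. Of 24 cholesterol synthesis and uptake genes 24 were higher, with a median of 0.52 (0.46 to 0.55). Mvd, an enzyme of the mevalonate pathway (mm10 chromosome 8, 122433601 to 122443422), was at 34.5 and 84.5 CPM, a ratio of 2.45 (2.11 to 2.86), with Fdft1 at 112 and 204 CPM and Msmo1 at 112 and 182 CPM. Of 13 fatty acid synthesis genes 13 were higher, with a median of 0.45, led by Acss2 (29.4 to 65.1 CPM), Fasn (60.2 to 107 CPM) and Scd1 (68.7 to 120 CPM). The LXR targets had a median of 0.24 with 6 of 7 higher, and its call ended under 8 alternatives (0.051 to 0.25).

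The bile acid synthesis, xenobiotic and hepatocyte maturation lists were written after the data had been opened, so their calls were not planned. Bile acid synthesis genes of hepatocyte-like cells had a median of -0.13 with 6 of 10 lower, and the call ended among male cells (-0.042). Cyp7a1, the first enzyme of the classical pathway, was at 41.4 and 24.0 CPM and Cyp8b1 at 39.6 and 30.2 CPM. The xenobiotic genes had a median of 0.24 with 4 of 7 higher, led by Cyp3a11 (30.2 to 99.5 CPM), and the hepatocyte maturation genes -0.06 with 10 of 16 lower, which was 0.067 at equal weights of clusters, where the call ended. G6pc (38.5 to 5.00 CPM) and Pck1 (16.5 to 1.82 CPM), enzymes of glucose production, were the farthest in that list. The immediate early genes had a median of 0.28 with 8 of 11 higher, the inflammatory genes 0.38 with 3 of 3 higher, and the glucocorticoid targets -0.06 with 5 of 10 lower, a median that was 0.50 at a minimum of 200 UMIs. The immediate early call ended under 6 alternatives (0.11 to 0.23), the glucocorticoid call under 5 (-0.048 to 0.15) and the xenobiotic call under 4 (0.093 to 0.22). The inflammatory call ended as a mean over cells (0.21) and in cells with at least 1000 genes (0.15). The largest ratios were of Elane (9.45 to 101 CPM), Prtn3 (23.3 to 140 CPM) and Hamp, the iron hormone hepcidin (19.3 to 91.1 CPM). Elane and Prtn3 are neutrophil granule genes, whose list was at 1.17 with 8 of 8 higher and at 0.71 without called doublets; remaining doublets and free RNA were not set apart. The smallest were of Txnip, which follows glucose (361 to 57.2 CPM), G6pc and Igfbp2 (226 to 81.1 CPM).

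**Figure D4:**
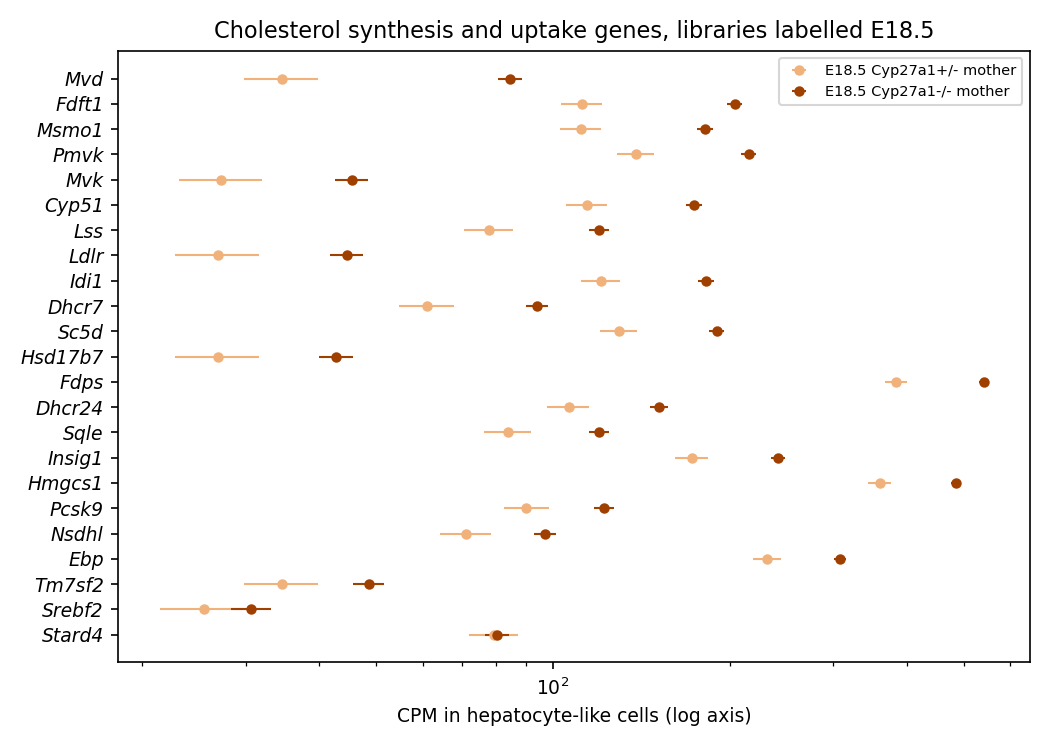
Points show CPM of cholesterol synthesis and uptake genes in hepatocyte-like cells of the 2 libraries labelled E18.5, on a log axis, with exact 95% Poisson intervals. All 24 genes were higher with the null mother, of which 1 is not drawn, and Mvd was at 34.5 and 84.5 CPM.

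In endothelium-like cells of the libraries labelled E18.5, 571 and 503 cells, matrix genes were lower with the null mother and stress genes were higher. The matrix lists, looked at here after values were seen, were at -1.28 for elastic fibre with 5 of 5 lower and -0.40 for collagens with 3 of 3 lower. An unnamed cluster of 280 and 161 cells had Dcn, Col3a1 and Col1a2 among its leading genes. Its gut and pancreas genes were nearly all with the heterozygous mother (Fabp2 6150 UMIs and 1 UMI). Carry-over of such cells or their RNA was not tested, so the matrix values may not be a trait of endothelium-like cells. The endothelial genes had a median of -0.16 with 7 of 9 lower, led by Emcn (173 to 126 CPM), the S phase genes -0.21 with 11 of 15 lower, the G2 and M phase genes -0.16 with 12 of 16 lower, and the hypoxia genes -0.12 with 10 of 15 lower. The unfolded protein response had a median of 0.17 with 10 of 13 higher, the immediate early genes 0.16 with 10 of 12 higher, and the interferon genes 0.27 with 10 of 12 higher. The last 2 lists were at -0.11 each among male cells, where the calls of endothelial, S phase, hypoxia and collagen genes ended as well (-0.058, -0.25, -0.045 and -0.12). The S phase and G2 and M phase calls also ended without cells above the 95th percentile of UMIs (-0.077 and -0.079), and the endothelial and immediate early calls in cells with at least 1000 genes (-0.14 and 0.082). At a minimum of 200 UMIs the hypoxia and immediate early calls ended (-0.11 and 0.12), and without called doublets the S phase call (-0.20). The cholesterol list was at 0.03 with 4 of 7 higher, inside the central 95% of random lists. The largest ratios, Ttr (50.5 to 235 CPM), Apoa2 (46.0 to 187 CPM) and Rbp2 (6.31 to 39.8 CPM), include genes of hepatocytes, whose list was at 1.29, and at 1.09 without called doublets; remaining doublets and free RNA were not set apart. The smallest were of Mgp (266 and 0 UMIs, at least 102-fold lower), Eln (232 and 5 UMIs) and Fbln2 (171 and 13 UMIs).

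Immune cells of the libraries labelled E18.5, 7882 and 7921, were mainly neutrophils, monocytes and B cell precursors. Stress, interferon and cholesterol genes were higher with the null mother, and mast cell and basophil genes were lower. Of 15 unfolded protein response genes 13 were higher, with a median of 0.37, of 14 interferon genes 14 were higher, with a median of 0.30, led by Isg15 (601 and 1656 UMIs), and of 23 cholesterol genes 21 were higher, with a median of 0.14. The interferon median was 0.04 among male cells, inside the central 95% of random lists. The LXR targets were at 0.16 with 9 of 10 higher, and at -0.06 when clusters had equal weights, the hypoxia genes at 0.13 with 11 of 17 higher, and the Wnt targets at -0.13 with 4 of 4 lower. The calls of these 3 lists ended as means over cells (0.094, 0.094 and -0.037), that of LXR targets at the equal weights as well, and that of Wnt targets at a minimum of 10 UMIs (-0.019). Macrophage genes were at 0.89 with 6 of 7 higher, led by C1qb (171 to 389 CPM), and at -0.24 when clusters had equal weights; the macrophage cluster held 5.20% and 7.89% of the class.

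Within the immune class labelled E18.5, the mast cell and basophil genes were at -0.53 with 5 of 5 lower, led by Mcpt8 (109 to 24.7 CPM), the megakaryocyte genes at -0.17 with 3 of 4 lower, and the neutrophil and monocyte genes at -0.16 with 7 of 7 lower. At equal weights of clusters the neutrophil median was -0.0012, the mast cell median -0.10 and the megakaryocyte median 0.0063, and all 3 calls ended. The neutrophil and megakaryocyte calls also ended in cells with at least 1000 genes (-0.076 and -0.11), the neutrophil call among male cells (-0.10), and the megakaryocyte call without called doublets (-0.16); the megakaryocyte median was 0.21 among male cells. Both granule lists, added after the data were seen, moved apart: azurophil granules, which form early, were at 0.57 with 8 of 8 higher, and specific and gelatinase granules, which form later, at -0.36 with 9 of 10 lower, led by Retnlg (1745 to 837 CPM). The mix of clusters went with this: the cluster led by Elane held 6.86% and 11.6% of the class, and clusters led by Mmp8 and by Retnlg held 16.9% and 12.2%, and 6.04% and 2.35%. At equal weights the granule medians were 0.25 and -0.14. The hepatocyte list was at 1.54 with 5 of 5 higher, and hepatocyte-like cells were more frequent in that library. The 3 largest ratios were of Marco, a scavenger receptor of macrophages (56.6 to 253 CPM), Ttr and Apoa2, and the 3 smallest of Ctrb1, a pancreatic enzyme (1508 and 0 UMIs, at least 626-fold lower), Mcpt8 and Prss34 (101 to 33.0 CPM).

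By cell type, chosen after the data were seen, the cholesterol list was at 0.16 in neutrophils and monocytes with 19 of 22 higher, at 0.23 in lymphoid cells with 15 of 16 higher, and at 0.24 in macrophages with 12 of 13 higher, the last inside the central 95% of random lists. The lymphoid call ended at a minimum of 200 UMIs (0.21) and among male cells (-0.11). The interferon list was at 0.27, 0.25 and 0.19 in the same order. Among male cells it was at -0.08, 0.28 and -0.12, all inside the central 95% of random lists, and the lymphoid call also ended at a minimum of 10 UMIs (0.052) and at equal weights (0.15). Erythroid cells, 6029 and 3313, had an all-gene median of 0.21, and the cluster holding the largest part differed: cluster 2 held 29.5% with the heterozygous mother and cluster 0 held 53.7% with the null mother, while cluster 8 held 25.2% and 1.45%. The medians and counts that follow do not have that all-gene shift taken off, and it was 0.077 at equal weights of clusters. Cholesterol genes were at 0.33 with 20 of 20 higher and G2 and M phase genes at 0.45 with 16 of 16 higher. The unfolded protein response was at 0.41 with 12 of 13 higher, and immediate early genes at 0.36 with 12 of 12 higher. The G2 and M phase call ended in cells with at least 1000 genes (0.071), at equal weights (0.095) and among male cells (0.047). Those of the unfolded protein response and immediate early genes ended as means over cells (0.48 and 0.39), and those of cholesterol and immediate early genes at a minimum of 200 UMIs (0.35 and 0.36), though these medians were no smaller than the main ones. The erythroid genes were at -0.31 with 7 of 9 lower. The S phase median of 0.04 was below the shift, but as a mean over cells it was 0.39, above the shift of 0.30 there, and its call ended. Bpgm (449 to 136 CPM), Mkrn1 (839 to 429 CPM) and Cd36 (31.3 to 12.8 CPM) had the smallest ratios, and Apoa2, Ttr and Afp, genes of hepatocytes, the largest.

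The maternal difference was then set side by side at both ages. Across 5805 genes measured in endothelium at both ages, the log2 ratios had a Pearson correlation of 0.0437, and across 5462 genes in immune cells -0.0679. Erythroid cells, not a planned class, had a higher one of 0.315 across 545 genes. Genes are not independent replicates, and the contents of the libraries differed between the ages, so these describe the libraries alone. In endothelium 11 genes were at least 1.5-fold apart at both ages. Of these, 8 had the same sign (72.7%), where 76.0% would if the ages were independent, so there was no excess. Eln, Fbn1, Fbln2, Fbln5 and Mgp were among the 8, and carry-over of mesenchymal RNA was not tested. In immune cells 10 of 18 such genes had the same sign, where 55.6% would, and in erythroid cells 4 of 4, where 50% would.

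The last comparison was of E18.5 over E14.5 within each mother, over non-erythroid cells, and it mostly describes the change of tissue. Hepatocyte genes were higher by a median of 7.45 with the heterozygous mother and 9.02 with the null mother, neutrophil and monocyte genes by 9.68 and 9.42, lymphoid genes by 2.38 and 1.62, and macrophage genes by 0.83 and 0.75. Medians were -2.74 and -2.75 for mesenchyme, -3.38 and -3.31 for smooth muscle, -2.62 and -2.94 for elastic fibre, -1.69 and -2.31 for epithelium, and -0.98 and -1.18 for AT1 genes. The AT2 and surfactant medians of -0.51 and -0.41, and the endothelial median of -0.77 with the heterozygous mother, lay inside the central 95% of random lists; the endothelial median of -1.70 with the null mother did not. Interferon genes were at 0.99 and 0.88. The cholesterol list was at -0.56 with the heterozygous mother, inside the central 95%, and at 0.41 with the null mother, with 5 and 19 of 24 genes higher.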

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

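The tests below were chosen after the results had been seen. The predictions on stage, sex and feeding were written before their test values were computed, and the others after. The list medians that differ in sign between the ages were picked by a fixed rule, and differences between the ages were not tested.

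Surfactant and AT1 genes were higher in E14.5 epithelium of the null mother's library. Free RNA would give a like gain in mesenchyme, but 13 of 16 genes (81.25%) gained over 4 times as much CPM in epithelium. With clusters at equal weights the median of both lists together was 0.60, against 0.53, so the mix of the named clusters does not account for it. A shift of cell states within a cluster could not be seen this way. Growth genes of early fetal tissue that had not been looked at (Igf2bp1, Igf2bp2, Hmga1 and Trim71) had a median below 0 in 3 classes, -0.25 in epithelium, -0.25 in mesenchyme and -0.16 in endothelium, the last at percentile 3.54 and so inside the central 95%, with too few measured in immune cells, so the fetuses of the null mother may have been older in development when taken. A stage difference and an effect of the mother's genotype remain open, as 1 library per group cannot part them.

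The libraries labelled E18.5 had hepatocyte genes and almost no lung genes. Hepatocyte genes were at a median of 311 and 109 times the CPM in hepatocyte-like cells that they had in endothelium-like cells. The hepatocyte-like clusters were named by these same genes, so a high ratio was favoured beforehand. It is therefore no test of free liver RNA in lung. Lung with liver cells mixed in does not account for the pattern, since Nkx2-1 was at 0.0993% and 0.0161% of its E14.5 CPM. The hepatocyte list was 7.45 higher in log2 than at E14.5, at the least, with lung lists below 0, which restates the pattern. These libraries may be fetal liver, or another mislabelled sample, and the label remains unexplained.

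Cholesterol synthesis genes were higher in hepatocyte-like cells of the null mother's library labelled E18.5. Sex does not account for it: among male cells the median was 0.60, from 323 and 699 cells. Nor does the mix of the named clusters, with 0.45 at equal weights, though a shift within a cluster could not be seen. Fasting genes that had not been looked at (Irs2, Ppargc1a, Cpt1a, Pdk4, Klf15 and Sesn1) had a median of -0.33, below all but 0.01% of random lists, so a difference in feeding or hour of collection may be part of it. Igfbp1 (1850 to 781 CPM), Lpin1 (777 and 1285 UMIs, 0.425 times the CPM) and Angptl4 (47.8 to 23.8 CPM), chosen after being seen, went the same way, and an effect of the mother's genotype remains open. Stage was not tested in these libraries. Within the null mother's library the cholesterol list was at -0.31 in female over male hepatocyte-like cells, so a difference between fetuses remains open as well. The wild-type tag in the name of the heterozygous mother's library leaves the fetuses' own genotype unsettled, which bears on the comparison between the mothers too.

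Some lists had opposite signs at the 2 ages. In endothelium the unfolded protein response was at -0.19 at E14.5 and 0.17 at E18.5, and the endothelial list at 0.28 and -0.16. In immune cells the unfolded protein response was at -0.24 and 0.37, the lipofibroblast list at -0.58 and 0.38, AT2 and surfactant at 0.66 and -0.14, neutrophil and monocyte at 1.42 and -0.16, and the erythroid list at -0.19 and 0.29. Signs of 3 of these immune lists do not hold throughout: at E14.5 the erythroid median was 1.52 among male cells, 0.55 among female cells, 0.54 in cells with at least 1000 genes and 0.0062 as a mean over cells, and at E18.5 it was -0.14 at equal weights. At a minimum of 10 UMIs the E14.5 AT2 median was -0.14 and the lipofibroblast median 0.064, the latter 0.12 among male cells. The calls of both lists ended there, as did the E14.5 erythroid call as a mean over cells. Whether lists differ between the ages was not tested.

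Some cells fitted no planned class and were not analysed further. At E14.5, an unnamed cluster had 695 UMIs of thymic epithelium genes, nearly all with the null mother: Prss16 had 5 and 229 UMIs and Ccl25 had 6 and 177 UMIs. Heart muscle cells had 27394 UMIs of their own genes. In the libraries labelled E18.5, an unnamed cluster had 15528 UMIs of gut and pancreas genes, and nearly all were with the heterozygous mother: Fabp2 had 6150 UMIs and 1 UMI, and Ctrb1 had 2611 and 0 UMIs.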

How the results depend on the processing

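The alternatives with cells of one sex, without called doublets and with clusters at a resolution of 0.6 were chosen after the first results had been seen. Over the full set of lists, 2710 list medians stayed near the main value, 1131 moved and 69 changed sign, with 3611, 777 and 78 for named genes and 23, 6 and 2 for share ratios. Among reported values the counts were 781, 339 and 32 for list medians and 2118, 524 and 32 for genes. A change of sign was counted only where the main list median was called, or where the main interval of a gene or share ratio excluded equality. Other changes of sign are among the values counted as near or moved, so these are not counts of all sign changes. Alternatives by the authors' cell types were not possible, since the files hold none. All barcodes of the matrix were already in use. Female cells at E18.5 and called doublets at E14.5 were too few to apply. No paired analysis was possible because the libraries share no fetus or number. The cause of the changes below was not tested.

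With a pseudocount of 1 CPM, AT2 and surfactant in E14.5 epithelium was at 0.96, elastic fibre in E14.5 mesenchyme at 0.43 and cholesterol in E18.5 hepatocyte-like cells at 0.57. The correlation of endothelium across ages was 0.0643. E18.5 over E14.5, AT2 and surfactant was at -0.64 and -1.13 and hepatocyte at 9.99 and 11.72 (heterozygous and null mother).

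With at least 10 UMIs, AT1 and AT2 in E14.5 epithelium were at 0.46 and 0.41. The immune correlation was -0.0470, and AT2 across ages was at -0.011 and -0.16. With at least 200 UMIs, collagens in E14.5 endothelium were at 0.060 and glucocorticoid targets in hepatocyte-like cells at 0.50. The correlations were 0.126 in endothelium and -0.119 in immune cells, and AT2 across ages was at -0.54 with the null mother.

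As means over cells, AT2 and surfactant in E14.5 epithelium was at 0.40. In E14.5 mesenchyme, cholesterol was at -0.085, elastic fibre at 0.45, smooth muscle at -0.015, Acta2 at -0.28 and Myh11 at -0.015. In E14.5 endothelium, collagens were at 0.018 and Flt4 at 0.14. In E14.5 immune cells, G2 and M phase was at -0.31, Dhcr7 at -0.14 and Mgp at -0.0096. Pf4 in E18.5 immune cells was at -0.63, and the endothelium correlation was -0.103.

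With clusters at equal weights, glucocorticoid targets in E14.5 epithelium were at -0.012. In E14.5 mesenchyme, elastic fibre was at 0.26, smooth muscle at -0.22, mesothelium at 0.096, Acta2 at -0.22, Myh11 at -0.49, Upk1b at 0.096, Upk3b at 0.45 and Wt1 at 0.046. In hepatocyte-like cells, cholesterol was at 0.45 and hepatocyte maturation at 0.067. In E18.5 immune cells, LXR targets were at -0.061, macrophage at -0.24, megakaryocyte at 0.0063, Adgre1 at -0.000134, C1qa at -0.43, C1qb at -0.22, C1qc at -0.24 and S100a9 at 0.028. In E18.5 erythroid cells, S phase was at -0.13 and Hba-a2 at 0.036. The immune correlation was -0.0303.

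Among male cells, AT1 in E14.5 epithelium was at 0.68, cholesterol in E14.5 mesenchyme at -0.19 and Actc1 there at 0.70. In E14.5 endothelium, mesenchyme genes were at 0.23, collagens at 0.67, Ptprb at -0.031 and Tbx2 at 0.18. In E14.5 immune cells, immediate early genes were at -0.59, interferon at -0.0052, Ifitm3 at -0.0052, Nkg7 at 0.14 and Pdia4 at 0.029. Cholesterol in hepatocyte-like cells was at 0.60. In E18.5 endothelium, immediate early genes and interferon were at -0.11 each. In E18.5 immune cells, megakaryocyte was at 0.21, Csf3r at 0.023, Ifi27l2a at -0.13 and Ppbp at 0.059. S phase in E18.5 erythroid cells was at -0.13, interferon in neutrophils at -0.083 and in macrophages at -0.12, and cholesterol in lymphoid cells at -0.11. The correlations were 0.133 in endothelium and 0.0115 in immune cells.

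Among female cells at E14.5, AT2 and surfactant in epithelium was at 0.43, Tekt1 at -0.36, and elastic fibre in mesenchyme at 0.26. In immune cells, lymphoid was at -0.91, Cd3e at -0.57, Dhcr7 at -0.037 and Sdf2l1 at 0.066.

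Without cells above the 95th percentile of UMIs, G2 and M phase in E14.5 immune cells was at -0.066, hepatocyte maturation at 0.0073 and Pf4 in E18.5 immune cells at -0.87. The correlations were -0.0227 in endothelium and 0.00493 in immune cells. In cells with at least 1000 genes, glucocorticoid targets in hepatocyte-like cells were at 0.15, Csf3r in E18.5 immune cells at 0.069 and S phase in E18.5 erythroid cells at -0.17. The share ratios were 0.917 for mesenchyme, 1.54 for endothelium and 2.27 for immune cells at E14.5, and 3.79 for hepatocyte-like and 0.973 for immune cells at E18.5. The endothelium correlation was 0.0673.

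With median-of-ratios scaling, cholesterol in hepatocyte-like cells was at 0.42 and S phase in E18.5 erythroid cells at -0.17. Across ages, AT2 was at -0.26 and -0.17 and hepatocyte at 7.69 and 9.25. With totals without haemoglobin, mitochondrial and ribosomal genes, S phase in E18.5 erythroid cells was at -0.22, and across ages hepatocyte was at 7.92 and 9.45, and AT2 with the null mother at -0.48. With clusters at a resolution of 0.6, glucocorticoid targets in hepatocyte-like cells were at 0.000119. Without erythroid cells, E18.5 share ratios were 2.46 for hepatocyte-like, 0.734 for endothelium-like and 0.838 for immune cells.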

Other observations

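These observations, and the test in them, were chosen after the results had been seen.

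Interferon genes and cholesterol genes differed between male and female cells of one and the same library, that of the null mother labelled E18.5. In female over male cells, the interferon list was at 0.68 in immune cells with 14 of 14 higher, at 1.34 in endothelium-like cells with 9 of 9 higher, and at 0.93 in erythroid cells with 7 of 7 higher, but at 0.05 in hepatocyte-like cells, inside the central 95% of random lists. The cholesterol list was lower in female cells, at -0.31 in hepatocyte-like, -0.10 in immune and -0.42 in erythroid cells. Each sex may stand for a single fetus or a few, so this could be a difference between fetuses and not one of sex.

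The higher interferon genes in immune cells of the null mother's library labelled E18.5, 0.30 over all cells, were at 0.037 among male cells. The female cells, which the other library nearly lacks with 22 against 4411, may account for most of that difference over the class. Lymphoid cells do not settle it: the median was 0.25 over all cells and 0.28 among male cells, but 0.052 at a minimum of 10 UMIs and 0.15 at equal weights of clusters, the last 3 inside the central 95% of random lists.

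At E14.5 the embryonic share of beta-globin UMIs was 4.74% with the heterozygous mother and 1.31% with the null mother, and at E18.5 it was 0.00286% and 0.00479%. That share is mostly Hbb-y, and Hbb-bh1, also embryonic, went the other way in E14.5 erythroid cells with 63 and 289 UMIs. The globins therefore do not settle the stage of the fetuses, and the cause of their values was not tested.

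Cyp27a1 in E14.5 heart muscle cells was at 88.5 and 94.2 CPM, above the 31.9 and 30.5 CPM of epithelium. E14.5 erythroid cells had 0 and 4 UMIs.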
